A study of Homo sapiens with 6 samples.

How the data were processed

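T47D cells, a luminal breast cancer line that carries the oestrogen receptor, were transfected with a miR-489 mimic or with a scrambled control siRNA, and RNA was taken 72 h later, per the labels' protocols. Each group holds 3 samples with replicate numbers 1 to 3, each hybridised to a 1-colour Illumina BeadChip with biotin-labelled cRNA. The labels do not say whether replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The labels do not name the arm or sequence of the mimic.

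The deposited table that is not normalized gives, per the file headers, a summary intensity on a linear scale and a detection p-value for each of 47322 probes on each array. The software that made the deposited intensity values and detection p-values is not given in the sources used here. The authors also deposited a table of processed intensity values. The lumi package, version 3.2.2, is named in the submitters' processing notes, and its settings are not given in the sources used here. All 6 columns of that table have a median of 200.783 and a lowest value of 170.293, so the values are on a linear scale, and the transform behind them and any centring stay unknown. Across kept probes, after each probe's mean over the 6 arrays was removed, the log2 values of each processed column correlated with those of the array of the same sample at r from 0.978 to 0.988, and with those of any other array at no more than 0.799. These columns served as an alternative.

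The main values started from the deposited intensities. The background was estimated from the detection p-values and removed by normexp with an offset of 16 (nec in limma 3.58.1, R 4.3.3). Arrays were then quantile-normalized and log2 was taken. A probe was kept if its detection p was below 0.01 on at least 3 of the 6 arrays, whatever their group, which left 17104 probes (36.1%). Group differences were tested with lmFit and eBayes (two-sided, no trend, not robust), and p-values were adjusted by the Benjamini-Hochberg method over all kept probes. A probe, gene or list is called at an adjusted p below 0.05, and rose, fell or changed are used only of calls. Errors of log2 fold changes are standard errors from that fit. The number of arrays limits the precision, and signals near background have compressed or unstable folds.

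Probes were named from the platform annotation of 2016, with symbols looked up by Entrez identifier in a RefSeq gene table of GRCh38.p14, which was used for names only. Of all probes, 30113 had 1 symbol, 8 had several and 17201 were not listed and so stayed unnamed. The identifier matched for 30074 probes. Each gene was represented by its kept probe with the highest mean over all 6 arrays, which gave 10503 genes. For 38 of the 2684 genes with more than 1 kept probe, called probes moved in both directions. No coordinates are given because the sources used here name no genome build. A probe below the detection limit on every array of 1 group has only a bound there. Its fold is printed as "at least", from the mean of the bright group against the mean, over the dim group's arrays, of the higher of the probe's own value and the lowest value among probes detected on that array.

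Before the data were examined, 25 pathway lists and 5 lists of markers of other cell types were fixed, as was the rule for named genes. The rule takes the 12 largest rises and 12 largest falls among called genes whose arrays do not overlap between groups, leaving out provisional and pseudogene names, and all measured genes described as miR-489 targets. It adds from each list up to 4 called members with the largest fold, or the 2 with the smallest p where none is called. Genes outside it are said to have been chosen after their values were seen. The 25 lists with at least 5 measured members were tested by camera with a preset inter-gene correlation of 0.01, adjusted over lists. Camera with an estimated correlation and fry were alternatives.

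The other alternatives were no background correction, normexp with an offset of 50, median scaling, cyclic loess, the authors' processed values, 3 other filters on dim probes, the replicate number as a block, eBayes with trend and robust, array weights, the mean over a gene's probes, and leaving out each array in turn. Leaving out array 2 of both groups together was added after seeing the data. The fit and camera were tested on simulated data for the mimic against scramble comparison (19400 probes kept). The fit recovered 95.5% of probes changed 4-fold, 35.8% of those changed 2-fold and 0 of 67 changed 1.5-fold, with 3.33% of its calls false. Only 67 probes were changed 1.5-fold, 67 were changed 2-fold and 66 were changed 4-fold, against 33.9% of probes called in the real data. The adjusted p depends on that share, so these recovery rates do not carry over to the real comparison. The changed probes were drawn only from brighter kept probes, so the rates do not cover probes near background. Noise was drawn independently for each probe. The figures were drawn with matplotlib 3.10.9.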

Results

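Gene expression was measured in T47D breast cancer cells 72 h after transfection with a mimic of the microRNA miR-489 or with a scrambled control siRNA. Each group had 3 arrays. Mean probe intensity ran from 526 to 619 per array, and 16452 to 17346 of the 47322 probes were detected. Arrays of the same group correlated at r = 0.982 to 0.993 across kept probes, and arrays of different groups at 0.945 to 0.958. The leading principal component, with 67.7% of the variance, separated the groups. No pair of arrays within a group shared an identical intensity, so no column copies another of its group. That cannot tell separate cultures from repeat hybridisations, and all 6 were counted as separate samples. The question of the design is which genes change when miR-489 is raised in these cells.

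The array's probe for the miR-489 precursor transcript was detected on 0 of 6 arrays, and it does not measure the transfected mimic. Of the 8 genes listed beforehand as described miR-489 targets, 7 were measured. PTPN11, which encodes the phosphatase SHP2 of receptor tyrosine kinase signalling, fell 7.02-fold, with a log2 fold change of -2.81 ± 0.12 (SE, n = 3 per group, limma adjusted p = 4.80e-05). LAPTM4B, a lysosomal membrane protein gene, changed by -2.71 ± 0.19, and SUZ12, a core subunit of Polycomb repressive complex 2, by -1.47 ± 0.12. ULK1, the kinase that starts autophagy, fell by 0.83 on the log2 scale (SE 0.21). In all 4 genes each mimic array lay below each scramble array.

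SMAD3 (-0.15 ± 0.30), DEK (0.02 ± 0.12) and SPIN1 (0.16 ± 0.21, detected on 2 of 3 scramble arrays) were not called, and their signs changed under some alternatives. As a list, the targets had 0 members that rose, 4 that fell and 3 not called, over all probes and adjusted over the list alone (camera adjusted p = 0.0275). With an estimated correlation the list had an adjusted p = 0.896. LAPTM4B and ULK1 may have been picked as targets from these arrays, so their place in the list is not independent evidence of its direction. The ULK1 call was lost without scramble control array 2 (adjusted p = 0.0532) or 3 (0.0570), and without mimic array 1 (0.0661) or 3 (0.0682).

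**Figure D1:**
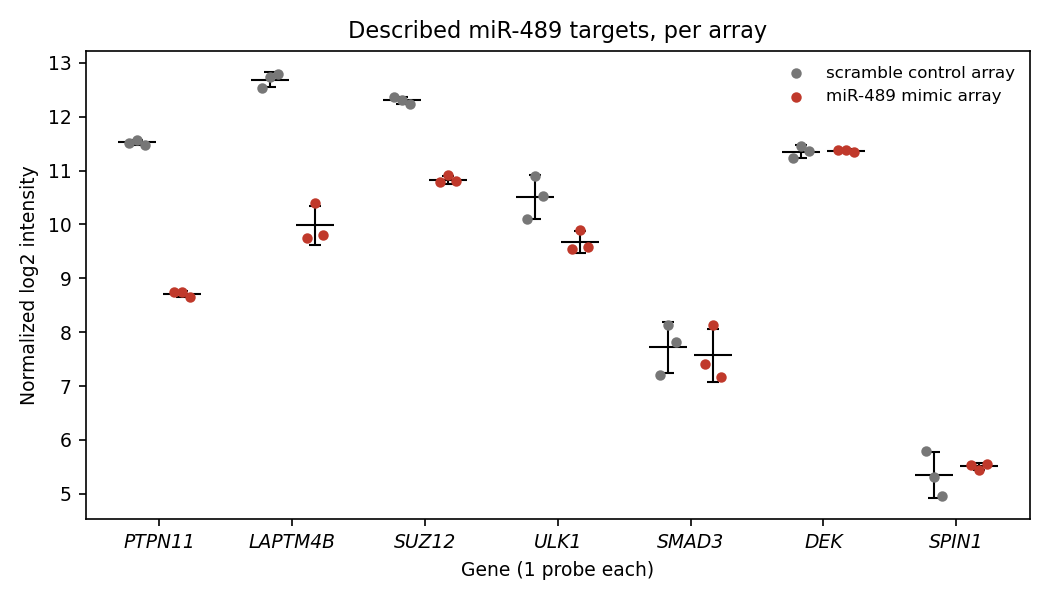
Normalized log2 intensity (vertical axis) of the 7 measured genes described as miR-489 targets, 1 probe each, on the 3 scramble control arrays (grey) and the 3 miR-489 mimic arrays (red); horizontal bars are means and error bars SD. PTPN11, LAPTM4B, SUZ12 and ULK1 lay lower on every mimic array, and SMAD3, DEK and SPIN1 overlapped between groups.

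Among the 12 largest fitted rises, the probes of PLAC8 and GJA1 were detected on 1 of 3 scramble arrays and that of EFNB2 on 2, so their scramble means rest partly on signal at background and the sizes below are uncertain. PLAC8 changed by 4.80 ± 0.28 (2.21 in the authors' values, below MT1X at 2.42 and ACTA2 at 2.22), EFNB2, the ephrin-B2 ligand, by 3.89 ± 0.36 (1.98), and GJA1, the gap junction protein connexin 43, by 3.81 ± 0.19 (1.65). MT1X, a metallothionein whose paralogs are close in sequence, changed by 3.43 ± 0.35, and DAB2, an endocytic adaptor, by 3.23 ± 0.13. RASL11B, a Ras-like GTPase, changed by 2.78 ± 0.21 and THEM4, a thioesterase, by 2.75 ± 0.13. The probes of 4 further genes were below detection on all scramble arrays: ODAM rose at least 6.02-fold, the cadherin CDH10 at least 5.96-fold, the receptor ADGRL2 at least 4.48-fold (2.76-fold without mimic array 2) and the glutamate transporter SLC1A3 at least 3.93-fold. ACTA2, smooth muscle actin, changed by 2.58 ± 0.65 (3.34 without scramble control array 2), and its call was lost without scramble control array 3 (adjusted p = 0.0626), without a filter on dim probes (0.0548) and with trend and robust (0.0815). In the authors' values, on a more compressed scale, these bounds do not hold: ODAM was at log2 1.03, CDH10 at 0.93, SLC1A3 at 0.71 and ADGRL2 at 0.81 (not called, adjusted p = 0.0603). DAB2 was there at 1.54, RASL11B at 2.10 and THEM4 at 1.16.

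Among the 12 largest fitted falls was CADM1, a cell adhesion molecule, with a log2 fold change of -4.17 ± 0.21 (adjusted p = 5.33e-05). The neighbouring ABC transporter genes ABCC12 and ABCC11 both fell, ABCC12 at least 11.5-fold with no detection on any mimic array, and ABCC11 with a log2 fold change of -3.48 ± 0.19. SRARP, which encodes a regulator of steroid receptors, changed by -3.52 ± 0.27, and OAS2, an interferon-induced synthetase, by -3.38 ± 0.73 (-4.18 without mimic array 2). The probes of OAS2 and CGNL1 were detected on 1 of 3 mimic arrays, so the sizes of these 2 falls are uncertain. GPC6, a glypican, changed by -3.03 ± 0.15, BRWD1, a bromodomain protein, by -2.97 ± 0.15, SYN1, a synapsin, by -2.89 ± 0.27, the glycosyltransferase B3GALNT1 by -2.89 ± 0.14 and the junction protein CGNL1 by -2.88 ± 0.45. CCDC85A fell at least 5.22-fold and FOXJ1, a transcription factor of motile cilia, at least 4.43-fold. In the authors' values these bounds do not hold either, with ABCC12 at log2 -1.56, CCDC85A at -0.90 and FOXJ1 at -0.81. The other falls were smaller there too, with CADM1 at -3.07, SRARP at -2.38, ABCC11 at -1.96, BRWD1 at -1.77, B3GALNT1 at -1.69, GPC6 at -1.48, OAS2 at -1.43, SYN1 at -1.33 and CGNL1 at -1.18.

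In limma, 5798 of 17104 probes (33.9%) were called, 3002 higher and 2796 lower with the mimic, and 4342 of them changed at least 1.5-fold. Of 10503 genes, 3752 were called (35.7%), 1933 higher and 1819 lower, and in 3732 of them the arrays did not overlap between groups. The counts of calls in the gene lists below are to be read against that share, and several lie near it. Over all kept probes, 48.8% had groups that did not overlap, against 10% by chance for 3 against 3. Among genes with a fold of at least 4, 42 rose and 67 fell. Leaving out any 1 array lowered the number of called genes to between 2536 and 3592. A lower count in a list without 1 array, as given below, can thus follow from fewer calls over all genes. Median scaling moved the median log2 fold change of kept probes to 0.10 and split the calls into 3676 higher and 2210 lower. The count of 4-fold genes fell from 109 to 35 with an offset of 50, 23 without background correction and 14 in the authors' values, and 1.5-fold probes to 2267 without background correction and 1503 in the authors' values. In the authors' values the folds of 53 of the 117 called named genes were over 1.5 times smaller, among them PLAC8 (log2 2.21) and CADM1 (-3.07), and those of all 14 called named genes with only a bound lay under that bound.

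Most measured genes of the oestrogen response fell. Of 30 measured members, 19 fell, 3 rose and 8 were not called (21 fell and 3 rose adjusted over the list alone), with a median log2 fold change of -0.96 (camera adjusted p = 6.13e-06). With an estimated correlation (0.0331) the adjusted p = 0.344. CA12, a carbonic anhydrase, changed by -2.16 ± 0.14, RERG, a Ras-like growth inhibitor, by -1.97 ± 0.13, TFF3, a secreted trefoil peptide, by -1.89 ± 0.32 and KCNK5, a potassium channel, by -1.79 ± 0.35. ESR1, the oestrogen receptor gene, chosen after its value was seen, changed by -1.16 ± 0.12. The members that rose, also named after their values were seen, were the chaperone genes HSPB8 (1.16 ± 0.21) and FKBP4 (0.61 ± 0.18) and the zinc transporter SLC39A6 (0.45 ± 0.13). The count that rose was 1 without scramble control array 2, mimic array 1 or mimic array 3.

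The luminal and epithelial identity list had 11 members that fell, 4 that rose and 6 not called of 21 (12 fell and 4 rose adjusted over the list alone), and it missed the threshold (camera adjusted p = 0.0572). It passed without scramble control array 1 (0.0481), without mimic array 2 (0.0247) and without array 2 of both groups (0.0301), an alternative chosen after seeing the data, and under 10 of 14 other analyses with all 6 arrays, among them the authors' values and fry. With an estimated correlation the adjusted p = 0.896, and the list was called in 1 of 9 other splits of the arrays. These splits mix the groups and keep part of their difference, so they are no null and cannot judge the list's p. TRPS1, a GATA-type transcription factor, changed by -2.18 ± 0.17, the keratin KRT7 by -1.65 ± 0.19, SPDEF, an epithelial ETS factor, by -1.58 ± 0.14 and the tight junction scaffold TJP1 by 1.40 ± 0.18. It held 7 that fell and 2 that rose without mimic array 1, 1 that rose without mimic array 3 and 2 without scramble control array 2. Of the mesenchymal transition list, 10 members were measured, of which ACTA2 rose and 2 fell, the integrin ITGA5 (-1.28 ± 0.21) and MMP9, a matrix protease (at least 1.40-fold), which was not called in the authors' values (adjusted p = 0.0656). Its median (-0.08) and mean (0.13) differ in sign (camera adjusted p = 0.830). 1 member rose, against 0 without scramble control array 3 and 2 without scramble control array 1 or 2.

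**Figure D2:**
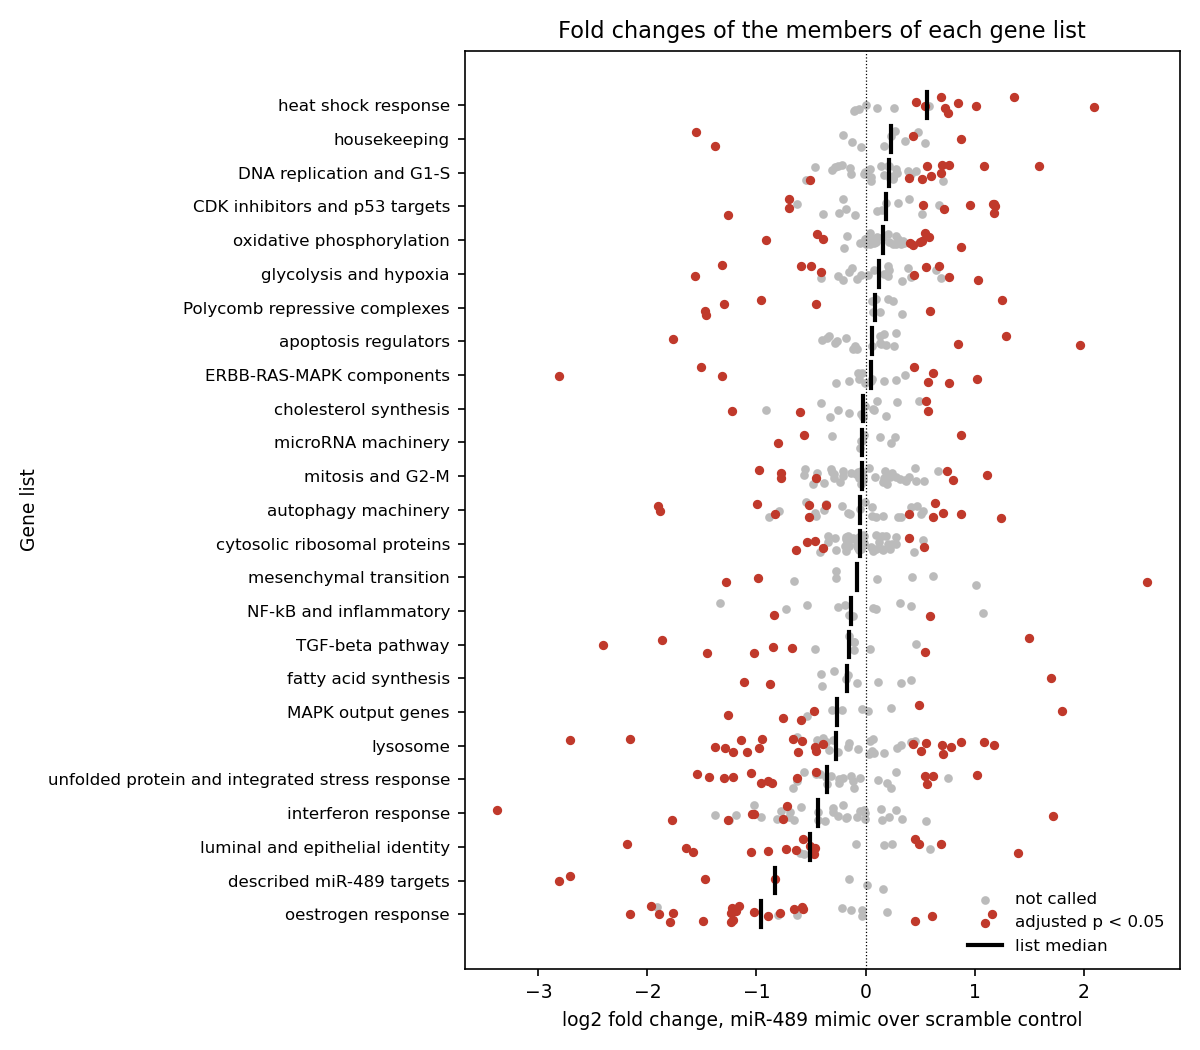
Log2 fold change, miR-489 mimic over scramble control (horizontal axis), of each measured member of the 25 tested gene lists, 1 row per list, with 3 arrays per group; red points are called in limma at an adjusted p below 0.05, grey points are not, vertical spread within a row is random and black bars mark list medians. The oestrogen response list has the lowest median (-0.96) and the heat shock list the highest (0.56).

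Lysosomal genes moved in both directions. Of 46 measured, 15 fell, 9 rose and 22 were not called (16 and 10 adjusted over the list alone; camera adjusted p = 0.153). The falls include LAPTM4B, reported above as a described target. The proton pump subunit ATP6V1C1 changed by -2.16 ± 0.13, the glucuronidase GUSB by -1.38 ± 0.13 and the lysosomal channel MCOLN1 by -1.29 ± 0.20. Without scramble control array 2, 9 fell. Of 35 autophagy genes, 7 fell, 6 rose and 22 were not called (10 and 7 adjusted over the list alone, camera adjusted p = 0.830). That share of calls is close to the 35.7% over all genes. ULK1, reported above as a described target, is among the 7 that fell. WIPI1, a phosphoinositide-binding protein, changed by -1.90 ± 0.21, the protease ATG4A by -1.88 ± 0.22 and ATG7, the E1-like enzyme of LC3 lipidation, by 1.24 ± 0.19. The count of autophagy genes that fell was 2 without scramble control array 3, 4 without scramble control array 2 and 3 without mimic array 1 or 3.

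Among 19 genes of ERBB-RAS-MAPK signalling, 3 fell and 5 rose (likewise adjusted over the list alone), with 11 not called. PTPN11, reported above as a described target, is among the 3 that fell. The receptor gene ERBB3 changed by -1.32 ± 0.22, PIK3R1, the regulatory subunit of phosphoinositide 3-kinase, by -1.50 ± 0.15 and GAB2, an adaptor that binds SHP2, by 1.03 ± 0.14. Its median was 0.05 and its mean -0.10, and camera gave an adjusted p = 0.830, upward. Fry, which tests the list against no other genes, gave downward at an adjusted p = 0.00746, and was not run without PTPN11. The count that rose was 3 without scramble control array 2 or 3 or mimic array 1 or 3. Among 12 MAPK output genes, 4 fell, 2 rose and 6 were not called (5 and 2 adjusted over the list alone; camera adjusted p = 0.644). FOS, an immediate early transcription factor, rose at least 2.17-fold and SPRY2, a feedback inhibitor, changed by -1.26 ± 0.23. In that list the count that fell was 1 without mimic array 3 and 2 without scramble control array 3, and 1 rose without scramble control array 2 or 3 or mimic array 3. In the TGF-beta pathway list of 15, 6 fell, 2 rose and 7 were not called, likewise over the list alone (camera adjusted p = 0.120). PMEPA1, a TGF-beta target and inhibitor, changed by -2.41 ± 0.14, the co-receptor TGFBR3 by -1.87 ± 0.22, the ligand TGFB3 by -1.45 ± 0.11, and the SMAD corepressor SKIL rose 2.82-fold. 1 rose without scramble control array 1 or any 1 mimic array.

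Of 39 genes of DNA replication and G1-S, 9 rose, 1 fell and 29 were not called (7 and 1 adjusted over the list alone; camera adjusted p = 0.132). The list was called upward without scramble control array 1 (0.0269), without mimic array 2 (0.00558), without array 2 of both groups (0.0203) and with array weights (0.0128). With an estimated correlation of 0.465 over all 6 arrays the adjusted p = 0.942. The list was called in 4 of 9 other splits, which mix the groups and are no null. RRM2, a ribonucleotide reductase subunit, changed by 1.59 ± 0.26, the DNA polymerase alpha subunit POLA1 by 1.09 ± 0.12 and the clamp loader subunit RFC5 by 0.70 ± 0.12. The count that rose was 4 without scramble control array 3 or mimic array 1, and 5 without scramble control array 2 or mimic array 3. UHRF1, the 1 that fell, was not called without scramble control array 1 or 2 or mimic array 1 or 2, and is named after its value (-0.51 ± 0.15) was seen. In the mitosis and G2-M list of 48, 41 were not called, 3 rose and 4 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.830), among them the proliferation marker MKI67 (-0.98 ± 0.13) and HMMR (0.81 ± 0.15). In that list 7 rose without mimic array 2, 5 without scramble control array 1 and 1 without scramble control array 3 or mimic array 1 or 3, and 2 fell without scramble control array 1 or 3. Among CDK inhibitors and p53 targets, 7 rose, 3 fell and 13 were not called of 23, likewise over the list alone (camera adjusted p = 0.766). CDKN1A, the CDK inhibitor p21, changed by 1.19 ± 0.17, GADD45A, a stress sensor, by 1.18 ± 0.23 and TNFRSF10B, a TRAIL receptor, by -1.26 ± 0.14. 4 rose without mimic array 3. Among 21 apoptosis regulators, 3 rose, 1 fell and 17 were not called, likewise over the list alone (camera adjusted p = 0.830). PMAIP1, a BH3-only gene, rose at least 1.82-fold and BMF, another, changed by 1.97 ± 0.46, with detection on 2 of 3 scramble arrays. BCL2, an inhibitor of apoptosis, fell at least 2.59-fold, and that call was lost without scramble control array 2 (adjusted p = 0.0510) or mimic array 1 (0.0510). BCL2 is also on the oestrogen response list. Without scramble control array 1, 2 apoptosis regulators fell.

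Heat shock genes rose or were not called. Of 16 measured, 9 rose, 0 fell and 7 were not called (10 rose adjusted over the list alone), with a median of 0.56 (camera adjusted p = 0.00605). With an estimated correlation the adjusted p = 0.896. The small chaperone gene CRYAB changed by 2.10 ± 0.23, HSPH1, an HSP110 chaperone, by 1.36 ± 0.13 and the mitochondrial chaperonin HSPD1 by 1.01 ± 0.12. HSPA1A, whose copy HSPA1B is nearly identical, changed by 0.85 ± 0.24, and its call was lost without scramble control array 2 or 3 or mimic array 1 or 3 (adjusted p from 0.0533 to 0.0871) and without a filter on dim probes (0.0669).

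In the unfolded protein and integrated stress response list of 35, 10 fell, 4 rose and 21 were not called (13 and 4 adjusted over the list alone; camera adjusted p = 0.0506). It passed without scramble control array 1 (0.0187), mimic array 1 (0.0439) or mimic array 3 (0.0325), and under 11 of 14 other analyses with all 6 arrays, among them the authors' values and fry. With an estimated correlation the adjusted p = 0.912. The list was called in 2 of 9 other splits, which mix the groups and are no null. The endoplasmic reticulum chaperone HYOU1 changed by -1.55 ± 0.19, the mitochondrial enzyme SHMT2 by -1.30 ± 0.17 and the secreted protein STC2 by -1.21 ± 0.18. STC2, XBP1 and SLC7A5 are also on the oestrogen response list, so these lists are not fully separate. SEL1L, a part of the degradation complex of the endoplasmic reticulum, fell at least 2.01-fold.

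Of 39 interferon response genes, 7 fell, 1 rose and 31 were not called, likewise over the list alone (camera adjusted p = 0.0506). IRF7, a transcription factor of the response, changed by -1.77 ± 0.28, PARP14 by -1.26 ± 0.28 and the immunoproteasome subunit PSMB9, detected on 2 of 3 scramble arrays, by 1.72 ± 0.34. Array 2 of each group stood apart in this list. The list median, relative to each gene's mean, was 0.67 on scramble control array 2 and 0.46 on mimic array 2, against -0.12 and 0.09 on the other scramble arrays and -0.55 and -0.46 on the other mimic arrays. With the correlation estimated over all 6 arrays (0.817) in place of the preset 0.01 the list had an adjusted p = 0.942. The calls that follow thus rest on the preset value. In 6 of 9 other splits, which mix the groups and are no null, the list was called too. Without mimic array 2, 17 genes fell (camera adjusted p = 2.14e-05), the list also passed without scramble control array 1 (0.00646) or 3 (0.0494), and without mimic array 1 or 3, 4 fell. Without array 2 of both groups, 18 fell and the adjusted p = 2.12e-05. Array 2 is the highest of its group in this same list, so leaving it out lowers the spread by selection. The p-values of fits without mimic array 2 are thus no independent support. The list also passed under 9 of 14 other analyses with all 6 arrays, but not in the authors' values (0.0584) or in fry (0.597). Of 14 NF-kB and inflammatory genes, 12 were not called (camera adjusted p = 0.830). SOD2, a mitochondrial superoxide dismutase (0.59 ± 0.14), rose, and TNFAIP3, an inhibitor of NF-kB (at least 1.29-fold), fell, and over the list alone 1 rose and 0 fell. The TNFAIP3 call was lost without scramble control array 2 or 3 or mimic array 1 or 3 (adjusted p from 0.0522 to 0.130) and under 5 other alternatives (0.0529 to 0.146), and the SOD2 call without mimic array 1 (adjusted p = 0.0523). In this list 3 fell without scramble control array 1 or mimic array 2, and 2 rose without scramble control array 2.

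**Figure D3:**
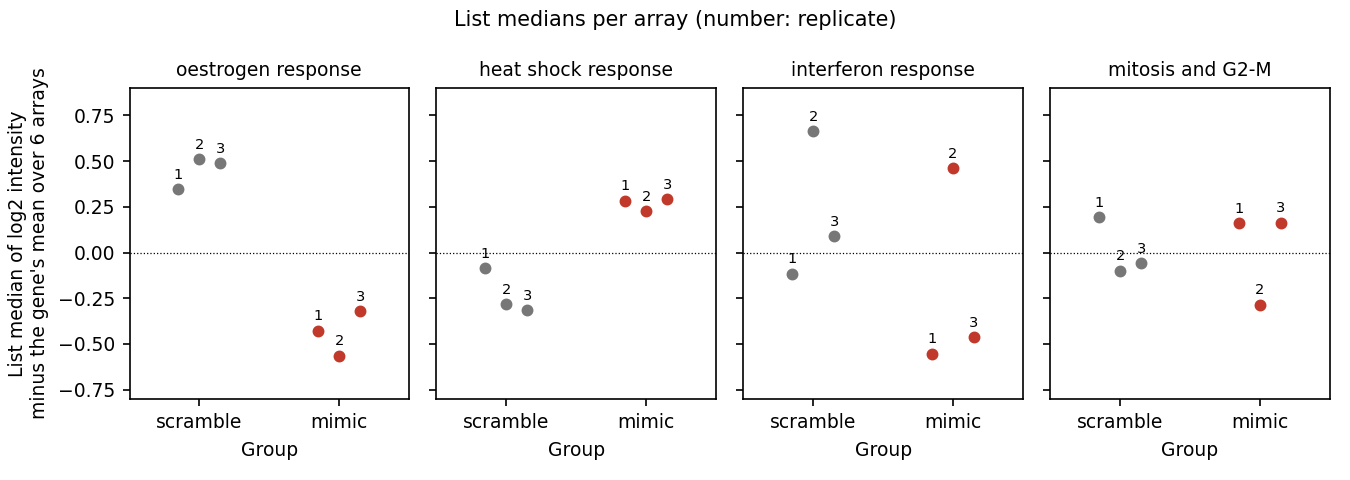
Median over the genes of 4 lists of the log2 intensity minus each gene's mean over the 6 arrays (vertical axis), for each scramble control array (grey) and miR-489 mimic array (red), with replicate numbers. The oestrogen and heat shock medians do not overlap between groups, while the interferon median of mimic array 2 (0.46) lies above those of scramble control arrays 1 and 3 (-0.12 and 0.09).

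Metabolic lists had calls in both directions, at a share no higher than the 35.7% over all genes, and none passed camera in the main analysis. Of 28 glycolysis and hypoxia genes, 5 rose, 5 fell and 18 were not called (8 and 5 adjusted over the list alone; camera adjusted p = 0.830), with the glucose transporter SLC2A1 at -1.56 ± 0.16, PFKFB3 at -1.31 ± 0.20 and the phosphofructokinase PFKP at 1.03 ± 0.15. Of these genes 2 rose without scramble control array 3 and 3 without scramble control array 2 or mimic array 3, and 3 fell without scramble control array 2 or 3 or mimic array 1. Of 33 oxidative phosphorylation genes, 7 rose, 3 fell and 23 were not called (7 and 2 adjusted over the list alone; camera adjusted p = 0.153), among them COX8A (-0.91 ± 0.11) and NDUFB5 (0.88 ± 0.14). It was called without a filter on dim probes (0.0453) and in fry, not in 12 of 14 other analyses with all 6 arrays, and with an estimated correlation the adjusted p = 0.942. Here 2 rose without mimic array 3, 3 without scramble control array 3 or mimic array 1 and 4 without scramble control array 1 or 2, and 1 fell without any array other than scramble control array 1. Among 12 fatty acid synthesis genes, the elongase ELOVL6 (1.71 ± 0.15) rose and 2 fell, the lipogenic regulator SREBF1 (-1.11 ± 0.12) and ACSL1 (-0.87 ± 0.16), likewise over the list alone (camera adjusted p = 0.766). Among 19 cholesterol synthesis genes 2 rose, 2 fell and 15 were not called, likewise over the list alone (camera adjusted p = 0.830), and 0 rose without scramble control array 2 or 3 or mimic array 1 or 3, and 1 fell without scramble control array 1 or 3 or mimic array 1 or 3. TM7SF2, a sterol reductase (-0.60 ± 0.14), was 1 of those that fell.

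Among 14 Polycomb genes, 5 fell, 2 rose and 7 were not called, likewise over the list alone. SUZ12, reported above as a described target, is among the 5 that fell. The histone-binding RBBP4 changed by -1.47 ± 0.17, PHF19 by -1.30 ± 0.27 and CBX2 by 1.25 ± 0.17. Its median (0.08) lies opposite to its mean (-0.19) and to camera, which pointed downward at an adjusted p = 0.830. 1 rose without scramble control array 2 or 3 or mimic array 1 or 3. Of 11 microRNA machinery genes, TNRC6A, a silencing complex scaffold (0.87 ± 0.13), rose, and 2 fell, among them the processing enzyme DICER1 (-0.80 ± 0.16), likewise over the list alone (camera adjusted p = 0.830). Leaving out any array other than scramble control array 2 left 1 that fell. Of 53 cytosolic ribosomal protein genes, 47 were not called, 2 rose and 4 fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.830), led by RPL36 (-0.63 ± 0.14). Of these, 2 fell without scramble control array 3 and 1 without scramble control array 1 or 2 or mimic array 1 or 3, and 0 rose without scramble control array 2 or 3 or mimic array 3 and 1 without scramble control array 1.

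Among 13 genes often used as housekeeping references, 2 rose and 2 fell, likewise over the list alone (camera adjusted p = 0.830). PPIA changed by -1.56 ± 0.14 and GUSB by -1.38 ± 0.13, and these signs held under each scaling. TBP, the TATA-binding protein, changed by 0.88 ± 0.13. The count that rose was 4 without mimic array 2 and 1 without any other array but scramble control array 2.

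Markers of other cell types were mostly below detection, and no such list reached 5 measured members for a test. The fibroblast list had 1 of 10 measured (COL1A1, -0.06 ± 0.20), the endothelial list 0 of 8 and the adipocyte list 1 of 6 (LEP, -0.36 ± 0.19), none of them called. Of 3 basal epithelial genes of 10, the receptor gene EGFR rose (0.76 ± 0.13), the integrin ITGB4 fell (-0.61 ± 0.15) and 1 was not called. Of 3 leukocyte genes of 10, CD14 (-1.34 ± 0.18) and CD68 (-0.59 ± 0.12) fell and 1 was not called.

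Of the 3 lists called by camera, all had the same direction in fry, and none was called with an estimated correlation. Fry, which tests a list against no other genes, also called the lysosome, TGF-beta, oxidative phosphorylation and Polycomb lists. It called the ERBB-RAS-MAPK, luminal and epithelial identity, and unfolded protein lists as well. None of these was called with an estimated correlation. With 3 arrays per group and no check that replicates were separate cultures, smaller differences may have gone undetected, and a call that misses the threshold does not show equality.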

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

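Leaving out array 2 of both groups together was chosen only after the result was seen. Under every alternative run the counts of called probes and genes stayed within 1.5 times of the 5798 and 3752 reported, and leaving out 1 array gave 3929 to 5569 probes, 2536 to 3592 genes, 3662 to 4545 probes at 1.5-fold and 102 to 129 genes at 4-fold. Probes at 1.5-fold numbered 2267 without background correction and 1503 in the authors' values, against 4342. Genes at 4-fold numbered 35 with an offset of 50, 23 without background correction and 14 in the authors' values, against 109. Background left in or a higher offset shrinks folds by construction, and in the authors' values the cause was not tested. All 117 called named genes kept their sign under each background correction and scaling, and folds shrank over 1.5 times in 53 of them in the authors' values, for example CADM1 to -3.07 and PLAC8 to 2.21 (log2). Of the 117, 24 lost the call without at least 1 array. Gene lists called by camera numbered 3, and 5 in the authors' values, 6 without background correction, with an offset of 50, with median scaling, with a detection p below 0.05, with a mean above the median, with trend and robust and without array 2 of both groups, and 7 without a filter on dim probes and with array weights. Fry called 10, camera with an estimated correlation 0 (1 at an unadjusted p below 0.05), and leaving out 1 array gave 3 to 7. The cause of these moves was not tested.

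The replicate numbers were not taken as pairs, since deviations from the group means correlated at 0.356 and 0.450 for numbers 1 and 2 but at -0.107 for number 3, and not every array correlated best with its own number; whether arrays 1 or 2 share a culture is not settled by this. With the replicate number as a block, 6680 probes, 4677 at 1.5-fold, 4260 genes, 109 genes at 4-fold and 5 gene lists were called. Values near 0 changed sign: SMAD3 ran from -0.43 to 0.057 when 1 array was left out (positive without scramble control array 2 or mimic array 3), DEK from -0.047 to 0.068 (negative without scramble control array 1), SPIN1 from -0.041 to 0.38 (negative without scramble control array 3) and COL1A1 from -0.17 to 0.16 (positive without scramble control array 3 or mimic array 1). DEK was also -0.020 with cyclic loess and -0.0098 with array weights, and COL1A1 0.042 with median scaling. The ERBB-RAS-MAPK list reversed in fry (adjusted p = 0.00746). The seed-site test and its alternatives were not run, since no transcript sequences were used here, and neither was the slide as a block, since no slide is given.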

Other observations

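The tests of the interferon pattern, of the 4-fold count and of leaving out array 2 of both groups were chosen only after the results were seen, as were the gene families. Gene families were read from shared symbol stems, 155 of them, and none passed camera. Semaphorins, guidance cues at the cell surface, came closest downward, with 6 of 13 that fell, 0 that rose and an adjusted p = 0.0542 (0.996 with an estimated correlation). SEMA6A changed by -2.05, SEMA4G by -1.74 and SEMA4D by -1.58, all named after their values were seen. Of 9 clustered protocadherin beta genes, 5 fell and 0 rose (adjusted p = 0.0654), and of 20 nucleoporins, 8 rose and 1 fell (adjusted p = 0.0654). Of 14 genes with the stem STK, 5 rose and 1 fell (adjusted p = 0.229), and of 16 with the stem INTS, 7 rose and 1 fell (0.412). Of 26 Mediator subunits, 11 fell and 4 rose (adjusted p = 0.412). On 223 probes signal was detected on all 3 scramble arrays and no mimic array, and on 186 the reverse.

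The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 5798 probes, 4342 at 1.5-fold, 3752 genes and 109 genes at 4-fold, in each case 1 of 10 splits, and the highest of the other splits called 0. Each other split mixes arrays of both groups, so the real difference widens the spread within its sides. Few calls there follow from that, so these splits are no null. At an unadjusted p below 0.05 limma called 7737 probes in the real split and 138 to 1620 in the other 9, the most where scramble control array 1 and mimic arrays 1 and 3 stood against the rest. For gene lists the real split called 3, the highest other split 7, and 9 of 10 splits called at least as many. The other splits keep part of the group difference, so they are no null for lists either. The number of lists called by camera with a preset correlation does not set the real split apart, and the reason was not tested.

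Oestrogen response genes were lower with the mimic. The median stayed at -0.70 or below under 5 other background corrections and scalings, so the choice among these does not account for it. They moved the median over all kept probes only to between -0.00634 and 0.102, so they cannot test a larger scaling error. The list median lay at percentile 0 of 10000 random lists matched on signal, which argues against a general fall of bright genes. It was -0.91 without array 2 of both groups. The list was also called in 6 of 9 other splits, but these keep part of the group difference and cannot judge its p. That p stays open, since the list was not called with an estimated correlation. No test here bears on how the mimic would act on the list.

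Heat shock genes were higher with the mimic. Without HSPA1A, HSPA1B and HSPA1L the median was 0.54, so cross-hybridization among the copies does not account for it. It lay at percentile 100 of matched lists and stayed at 0.53 or above under 5 other background corrections and scalings. The list was also called in 3 of 9 other splits, which mix the groups, and what lies behind the difference stays open.

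Interferon genes spread within groups, with a range of the list median of 0.78 over scramble arrays and 1.02 over mimic arrays. That mimic range lay at percentile 100 of matched lists. Random lists hold genes that need not move together, unlike this list (estimated correlation 0.817), so the percentile cannot decide on array-wide quality or scaling. Mimic array 2 also stood apart over all kept probes. Its array weight was 0.468, against 1.59 and 1.66 on mimic arrays 1 and 3. On the second principal component it lay at -32.1, against 15 and 13.9. Scramble control array 1, which was not high in this list, had a weight of 0.573 and lay at 26.1. Scramble control array 2, the highest in this list, had a weight of 0.981 and lay at -18.6. A state shared by cultures of the same number may be the source of the interferon spread, since arrays 2 were highest in both groups. The pairing gave an exact one-sided p of 0.167, the smallest that 6 pairings allow, so such a state cannot be told apart from chance. For scale, IFI27, named after its values were seen, ran from 6.15 to 12.35 over the mimic arrays.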
